A study of Mus musculus with 12 samples.

How the data were processed

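The series measured messenger RNA in mouse femur by sequencing on an Illumina HiSeq instrument. Per the labels' protocols, the diaphysis and the metaphysis were taken from femurs of 5-week-old males of mixed background, RNA was extracted with Trizol, and libraries were made with the TruSeq RNA kit, which does not mark the strand. A gene and an antisense partner therefore cannot be told apart, and near-identical copies such as Bglap with Bglap2 and the globin genes are uncertain. Groups were taken from the labels: diaphysis WT, diaphysis cKO, metaphysis WT and metaphysis cKO, 3 libraries each and 12 in all. Replicate numbers follow the order of the records, name a library only and pair nothing. The labels give no batch, litter or pairing.

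The authors deposited 1 table per region with a value per RefSeq transcript and library in RPKM, per the file headers. Reads were normalized by transcript length and library total by the authors before deposit. The submitters' processing notes name CASAVA 1.8.2, TopHat 1.3.2, Bowtie 0.12.7.0, Partek 6.6 and the genome build mm9, without saying what each did. The annotation release, the filters and the handling of reads shared by transcripts are not given in the sources used here. The diaphysis table held 24824 transcripts of 19067 gene symbols, and that of the metaphysis held 24456 transcripts of 18778 symbols, with 18335 symbols in both. The tables were made separately, so each region was tested within its own table, and across tables only differences between genotypes were tested. RPKM corrects for gene length and depth but not for composition. Where globin takes a larger share of a library, the other genes read lower there.

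Depth was worked out from the lowest values, which fall on whole multiples of what 1 read is worth for a transcript of a given length. This gave 18.6 to 54.4 M reads (M, mega) per library in the diaphysis (the lowest in cKO replicate 1, 26.4 M in WT replicate 1) and 24.8 to 35.0 M in the metaphysis. With these totals 71.9% to 75.8% of the low values lay within 0.1 of a whole number of reads, where chance gives 20%. Too many values were not whole for counts to be rebuilt, so no count test was run. On a transcript of 2 kb, 10 reads correspond to 0.269 RPKM in the shallowest library and 0.092 RPKM in the deepest, so values well below the RPKM minimum of 1 rest on few reads in the shallow libraries. The design had fixed a test for counts and another for normalized values, and the second was used because the values are RPKM.

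Transcripts were summed per symbol, and genes with at least 1 RPKM in 3 of the 6 libraries of a region were kept. Values were taken as log2(RPKM + 0.1), a scale on which the fold change of a low gene is understated. Each region was fitted by limma 3.58.1 (R 4.3.3) with a mean-variance trend and genotype as the factor, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference between regions was a contrast in 1 fit of all 12 libraries and 4 groups. Every adjusted p given for a gene is from these limma fits. Dlx3 was also tested by an exact 2-sided permutation test per region. Agreement between regions was read from overlap, from the share of metaphysis calls with the same sign in the diaphysis, tested by an exact permutation of the diaphysis genotypes, and from a fit of a genotype effect common to both regions, also run on every labeling of the diaphysis libraries with the metaphysis genotypes kept, the last 2 added after the separate results were known. WT levels of the regions were set side by side without a test. Preparation and summaries used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.

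Gene lists were tested with camera from limma at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction and compares them with no other genes. A list needed 5 measured members. The 29 lists cover osteoblasts, osteocytes, mineralization, homeobox and bone transcription factors, osteoclasts, osteoclast regulators from bone cells, Wnt signalling, BMP and TGF-beta signalling, chondrocytes and growth plate, bone matrix, proliferation, glucocorticoid and stress response, interferon response and oxidative phosphorylation. Others cover cell types a bone dissection can hold (skeletal muscle, erythroid, B lymphoid, neutrophil, monocyte, T and NK lymphoid, megakaryocyte, adipocyte, endothelial, tendon and periosteum, peripheral nerve, skin). The rest are ribosomal proteins and replication-dependent histones as signs of RNA quality, and a panel of 20 bone genes, which was left out of the adjustment over lists. Lists share members. A list score of a library is the mean log2 value of the list's genes, centred on the region's mean.

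Named genes followed a rule. It took Dlx3 and the 6 genes per direction with the largest fold change among those past the threshold whose 3 cKO values all lay on 1 side of the 3 WT values, leaving out gene models without a proper symbol and genes of the other-cell-type and RNA-quality lists. To these it added the bone panel and up to 4 members with the smallest p of each called list. A gene that the rule takes is not reported here. Where no gene passed, the 6 per direction with the smallest p were given without a call. Genes of the common fit and of the WT comparison beyond these, and all other members named, were chosen after their values were seen. The groups, tests, lists, naming rule and 56 alternatives were set before the data were examined, and 21 alternatives were added afterwards. Alternatives covered scaling between libraries, the filter, the pseudocount, the limma trend, array weights, the threshold, muscle, marrow and osteoblast scores as covariates, the choice of transcript, scaling without globin, all libraries in 1 fit, and leaving out each library in turn. Gene positions come from GENCODE vM1 on NCBIM37, the same assembly as mm9. Runx2 maps to several places in that annotation and is given without a position.

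The fits were tested on simulated data, 10 tables per comparison with 200 genes changed. At 2-fold, 29.4% of changed genes were recovered for the diaphysis, 71.0% for the metaphysis, 27.9% for the difference between regions and 80.4% for the effect common to both. At 4-fold these shares were 76.4%, 90.9%, 74.1% and 97.0%. At 1.5-fold the shares were 0.896%, 30.9%, 4.03% and 49.6%. False calls made up 5.61%, 4.40%, 6.02% and 4.00% of calls in these simulated tables. A list shifted by 0.5 on the log2 scale was called in 7 of 10 diaphysis tables and 10 of 10 metaphysis tables. These shares cannot be carried over to the real libraries, where genes of a list move together. The estimated correlation was 0.96 for the bone matrix list in the diaphysis. In the common fit with the metaphysis genotypes kept, other labelings of the diaphysis libraries called up to 1815 genes. Pearson's r of log2 values between libraries of a group was 0.907 to 0.981 across genes, and no pair shared more than a few identical values, so all libraries were counted as separate.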

Results

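Messenger RNA from the femurs of 5-week-old male mice was sequenced separately for the diaphysis, the shaft of the bone, and the metaphysis, the flared part next to the growth plate where new trabecular bone forms. Wild-type mice (WT) were set against mice with a conditional deletion of Dlx3 (Dlx3Oc-cKO in the labels, cKO from here on). Dlx3 encodes a homeobox transcription factor of the Distal-less family that is expressed in bone-forming cells. Each of the 4 groups held 3 libraries, 12 in total, and the labels gave neither batches nor pairs. The labels do not state in so many words that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, part of which may be technical. The titles of the 12 libraries begin with 12 different numbers, which may be animal numbers. The deposited values were RPKM, reads per kilobase of transcript scaled to the library's mapped reads. The spacing of the lowest values put the depth of a library at 18.6 to 54.4 M reads (M, mega) in the diaphysis and at 24.8 to 35.0 M in the metaphysis. Globin transcripts took 15.1% to 32.6% of the summed RPKM in the diaphysis and 13.5% to 22.1% in the metaphysis and marked the blood and marrow cells in each sample.

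Dlx3 itself (chromosome 11, 94981403 to 94986610, plus strand) was lower in all 3 cKO libraries than in all 3 WT libraries of each region. In the diaphysis its level was 7.97 ± 4.93 RPKM in WT (SD, n = 3; single values 3.22, 7.64 and 13.1) and 1.16 ± 0.39 RPKM in cKO, 14.5% of the WT mean. In the metaphysis it was 9.11 ± 0.86 RPKM in WT and 2.67 ± 0.64 RPKM in cKO (SD, n = 3), 29.4% of the WT mean. On the log2(RPKM + 0.1) scale Dlx3 fell by 1.75 with an SE of 0.18 in the metaphysis (limma, adjusted p = 0.00907). The diaphysis difference was -2.52 ± 0.50 (SE) and did not pass after adjustment over all genes (limma, adjusted p = 1.00). An exact two-sided permutation test gave p = 0.1 in each region, the smallest value that 3 against 3 libraries allow. The RPKM is a value for the whole gene, so it does not show which part of Dlx3 was lost. Its neighbour Dlx4 (chromosome 11, 95001770 to 95007577, minus strand), another Distal-less homeobox gene, went the other way. Dlx4 measured 0.577 ± 0.069 RPKM in metaphysis WT and 3.41 ± 0.44 RPKM in metaphysis cKO (SD, n = 3).

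**Figure D1:**
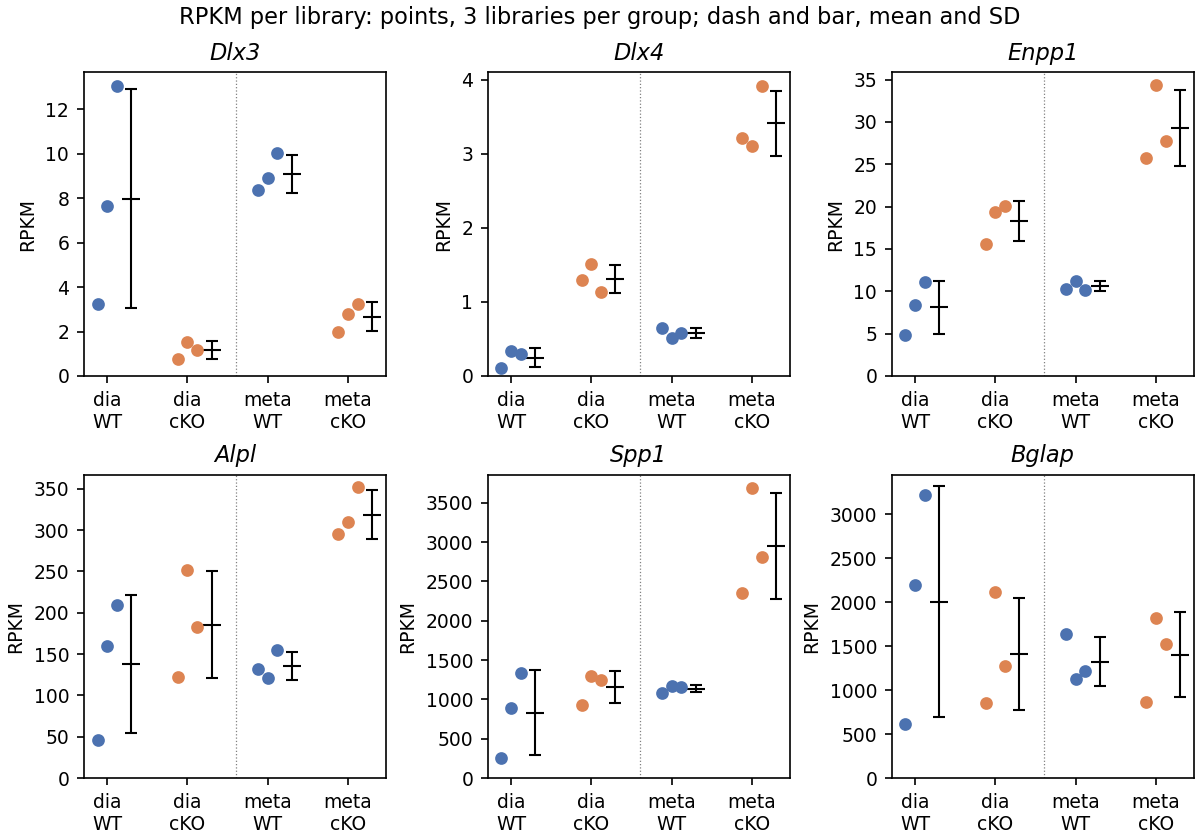
RPKM of 6 genes in each of the 12 libraries (points; dia, diaphysis; meta, metaphysis), with the mean and SD of the 3 libraries of a group beside them. Dlx3 was lower and Dlx4 and Enpp1 higher in every cKO library than in every WT library of the same region, while Bglap overlapped between genotypes in both regions.

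What loss of Dlx3 changes in the metaphysis was asked with the 6 metaphysis libraries. Camera placed lists of bone formation, mineralization, bone resorption and cartilage genes higher in cKO and lists of cell division, red cell precursor, B cell and platelet genes lower, while many of their members did not pass singly. With an estimated correlation 0 lists were called (smallest adjusted p = 0.0947). Of 12641 genes tested, 1441 passed an adjusted p of 0.05, 949 higher and 492 lower in cKO. Of these, 169 and 35 differed at least 2-fold. The rule for named genes leaves out gene models without a proper symbol and genes of the other-cell-type and RNA-quality lists. Under it, the largest rises among genes whose libraries did not overlap were Serpina3h (log2 fold change 3.95 ± 0.47 SE, adjusted p = 0.0101), the long noncoding RNA Miat (2.66 ± 0.18, adjusted p = 0.00369), the cartilage matrix gene Matn1 (2.50 ± 0.22, adjusted p = 0.00554), Emilin3 (2.48 ± 0.17), Dlx4 (2.37 ± 0.19, adjusted p = 0.00462) and Gsg1l (2.16 ± 0.18). Beside Dlx3, the largest falls under the same rule were Cd300ld, a receptor gene of myeloid cells (-1.77 ± 0.28, adjusted p = 0.0158), Nrip3 (-1.64 ± 0.36, adjusted p = 0.0318), Apol8 (-1.56 ± 0.21), Serpina3b (-1.47 ± 0.31) and the Schlafen gene Slfn8 (-1.47 ± 0.31). Cd300ld lies on chromosome 11, as Dlx3 does (114843588 to 114851236). Whether a linked chromosome segment differs between the genotypes there was not tested. In the metaphysis libraries 37.1% of the tested genes did not overlap between genotypes, where chance gives 10%. Without cKO replicate 3 the count was 105, and without WT replicates 1, 2 and 3 it was 188, 243 and 672. It was 8 when the diaphysis libraries shared the estimate of spread. With the mean score of the erythroid, B lymphoid and neutrophil lists, or of the osteoblast list, as a covariate, limma called 0 genes (1125 and 480 at an unadjusted p under 0.05). Even Dlx3 no longer passed in these 2 fits (limma, adjusted p = 0.391 and 0.678). Both scores move with the genotype, so these fits cannot tell the genotype from the make-up of the samples.

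Runx2 and Sp7, transcription factors that direct osteoblast formation, rose in the metaphysis. Runx2 went from 14.3 ± 1.63 to 27.7 ± 1.47 RPKM (adjusted p = 0.00943) and Sp7 from 63.8 ± 11.6 to 127 ± 7.64 RPKM (SD, n = 3; adjusted p = 0.0117). The related homeobox genes Dlx5 and Dlx6 rose by 1.38 ± 0.18 and 1.59 ± 0.27 (log2, SE). Of a panel of 20 bone genes, 19 were measured, 12 rose, 0 fell and 7 did not pass, and 15 rose when adjusted over the list alone. The panel overlaps genes the study is known for, so its direction is not independent evidence. Alkaline phosphatase (Alpl, 1.23 ± 0.12), bone sialoprotein (Ibsp, 1.18 ± 0.18) and osteopontin (Spp1, 1.35 ± 0.17) rose, whereas osteocalcin did not pass (Bglap 0.035 ± 0.28, adjusted p = 0.946; Bglap2 -0.0016 ± 0.23). Bglap and Bglap2 are near-identical copies whose reads cannot be assigned with certainty. Type I collagen (Col1a1 0.45 ± 0.16, adjusted p = 0.107) and the osteocyte genes Dmp1 (0.68 ± 0.19, adjusted p = 0.0596), Mepe (0.78 ± 0.32, adjusted p = 0.150), Phex (0.50 ± 0.18) and Sost (0.45 ± 0.36) did not pass either, and Fgf23 lay below the filter. Of the 67 named metaphysis genes past the threshold, 64 could be tested in each fit that left out a library. Serpina3h, Emilin3 and Dlx4 fell below the filter without a cKO library, and Cd300ld, Serpina3b and Slfn8 without a WT library. Of the 64 tested in each fit, 39 no longer passed without cKO replicate 3, Sp7, Dlx5, Dlx6 and Ibsp among them, 28 without WT replicate 1, 20 without WT replicate 2 and 12 without WT replicate 3, and 0 changed sign.

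Of 21 measured osteoblast genes 10 rose, 0 fell and 11 did not pass, 13 rising when adjusted over the list alone. Bmp3 (1.53 ± 0.11) and the parathyroid hormone receptor Pth1r (1.46 ± 0.13) led them, and camera called the list (adjusted p = 1.53e-07; adjusted p = 0.347 with an estimated correlation). In the mineralization list 11 of 17 were higher, 1 lower and 5 not past, and 15 higher and 1 lower when adjusted over the list alone. They included Enpp1, whose product makes the mineralization inhibitor pyrophosphate (10.6 ± 0.59 to 29.3 ± 4.52 RPKM), Phospho1 (1.25 ± 0.13) and the secretory kinase gene Fam20c (1.56 ± 0.16). Camera gave the mineralization list an adjusted p = 9.33e-09 and an adjusted p = 0.241 with an estimated correlation. Homeobox and bone transcription factors counted 9 of 23 higher and 14 not past, 14 higher when adjusted over the list alone (camera adjusted p = 1.23e-07; adjusted p = 0.188 with an estimated correlation). Among 16 osteocyte genes 6 rose, 1 fell and 9 did not pass, with 8 and 2 adjusted over the list alone. Mmp14 (0.88 ± 0.11) and Ptprz1 (1.12 ± 0.15) rose, and Pdpn, a gene of early osteocytes, fell by 1.08 with an SE of 0.19 (camera adjusted p = 0.00121; adjusted p = 0.425 with an estimated correlation). In the same libraries the erythroid, B lymphoid and megakaryocyte lists had mean log2 fold changes of -0.76, -0.61 and -0.53.

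Of 18 measured osteoclast genes, 11 rose in the cKO metaphysis and 7 did not pass (15 higher and 1 lower adjusted over the list alone), among them the resorption genes Acp5 (0.94 ± 0.14), Ctsk (0.69 ± 0.12) and Atp6v0d2 (0.84 ± 0.11) and the receptor gene Oscar (0.97 ± 0.16). Camera gave the osteoclast list an adjusted p = 6.05e-08 and an adjusted p = 0.241 with an estimated correlation. Of 13 genes through which bone cells regulate osteoclasts, 3 rose and 10 did not pass (5 higher adjusted over the list alone; camera adjusted p = 0.00966; adjusted p = 0.245 with an estimated correlation). The 3 were Csf1 (0.84 ± 0.11), the osteoclast differentiation factor Tnfsf11 (0.74 ± 0.19, adjusted p = 0.0472) and its decoy receptor Tnfrsf11b (1.34 ± 0.22, adjusted p = 0.0161). Tnfsf11 no longer passed when any single library was left out.

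Wnt genes counted 10 of 28 higher and 18 not past (14 higher and 1 lower adjusted over the list alone), led by Wnt10b (1.78 ± 0.16), Wnt5b (1.10 ± 0.13) and Tcf7 (1.20 ± 0.19). The Wnt list had a camera adjusted p = 5.23e-06 and adjusted p = 0.188 with an estimated correlation. BMP and TGF-beta genes counted 9 of 30 higher and 21 not past (13 higher and 1 lower adjusted over the list alone), among them Bmp8a (2.02 ± 0.27), Ltbp2 (1.96 ± 0.27) and Id3 (0.84 ± 0.14). Camera gave this list an adjusted p = 2.87e-06 and an adjusted p = 0.241 with an estimated correlation. In the chondrocyte and growth plate list 13 of 24 rose, 1 fell and 10 did not pass (16 higher and 1 lower adjusted over the list alone). Hapln1 (1.36 ± 0.18), Ihh (1.34 ± 0.19) and aggrecan (Acan, 28.9 ± 1.32 to 72.8 ± 18.2 RPKM) rose. The list mean was 0.95, and camera gave an adjusted p = 1.23e-07 and an adjusted p = 0.245 with an estimated correlation. The list score was -0.062, 0.82 and 0.66 in cKO replicates 1, 2 and 3 and -0.43, -0.23 and -0.76 in the WT replicates. Titles of the metaphysis libraries carry the letters GP and those of the diaphysis do not. Whether the samples differed in their share of growth plate was not tested. For bone matrix and its processing 15 of 39 rose and 24 did not pass (21 higher and 2 lower adjusted over the list alone), including Col22a1 (1.21 ± 0.15), Loxl1 (0.88 ± 0.11) and Col13a1 (1.20 ± 0.18). Camera gave the matrix list an adjusted p = 2.29e-07 and an adjusted p = 0.242 with an estimated correlation. Of endothelial markers 8 of 22 were higher and 14 not past (16 higher and 1 lower adjusted over the list alone). Plvap (0.93 ± 0.10), Emcn (0.95 ± 0.11), Sox18 (0.85 ± 0.13) and Cdh5 (0.60 ± 0.09) were the leading members (camera adjusted p = 1.12e-07; adjusted p = 0.0947 with an estimated correlation).

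Of 29 proliferation genes 11 fell in the cKO metaphysis and 18 did not pass, 27 falling when adjusted over the list alone. The replication clamp Pcna (196 ± 5.65 to 124 ± 22.8 RPKM), Birc5 (-0.67 ± 0.14), Top2a (-0.77 ± 0.17) and the mitotic kinase Aurka (-0.60 ± 0.13) were among them (camera adjusted p = 4.87e-11; adjusted p = 0.407 with an estimated correlation). Of 16 erythroid genes 5 fell and 11 did not pass (13 lower adjusted over the list alone), with Gata1 at -0.81 ± 0.19, Ermap at -1.05 ± 0.25 and the haem synthesis gene Alas2 at -0.72 ± 0.18 (camera adjusted p = 1.13e-06; adjusted p = 0.407 with an estimated correlation). B lymphoid genes gave 12 of 20 lower and 8 not past (14 lower adjusted over the list alone), among them Blk (-1.13 ± 0.15) and Pax5 (-0.98 ± 0.15). The B lymphoid list had a camera adjusted p = 7.28e-08 and adjusted p = 0.270 with an estimated correlation. In the megakaryocyte and platelet list 2 of 14, Ppbp (-0.69 ± 0.12) and Gp5 (-0.68 ± 0.14), fell and 12 did not pass (9 lower adjusted over the list alone; camera adjusted p = 0.000136; adjusted p = 0.433 with an estimated correlation). Camera also placed oxidative phosphorylation (32 measured, 0 past, mean -0.21, adjusted p = 0.677 with an estimated correlation) and skeletal muscle (24 measured, mean -0.76, adjusted p = 0.707 with an estimated correlation) lower. Of the muscle genes the myosin Myh1 (-1.30 ± 0.31, adjusted p = 0.0395) was the 1 past the threshold. The muscle call was lost without WT replicate 2, cKO replicate 1 or cKO replicate 3.

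Camera did not call every marrow list. The neutrophil and granulocyte list (mean -0.17, 1 higher and 20 not past), the monocyte and macrophage list (mean -0.069, 2 higher and 1 lower of 20) and the T and NK lymphoid list (mean -0.17, 1 lower of 12) were not called by camera, although fry called the last of these lower (adjusted p = 0.0192). Nor were the lists for glucocorticoid and stress response (2 higher of 25, mean 0.12 and median -0.0022), interferon response (1 higher of 25, mean -0.00093 and median -0.047 where the test pointed up), adipocytes (0 past of 18), tendon, periosteum and fibroblasts (2 higher of 20), peripheral nerve (1 higher and 1 lower of 8), ribosomal proteins (0 past of 38) and replication-dependent histones (0 past of 18). Camera called the neutrophil, adipocyte and tendon lists lower without WT replicate 3. It called the interferon list higher without cKO replicate 2 and lower without cKO replicate 3 (mean -0.31, camera adjusted p = 0.0354). Skin had 2 measured genes and was not tested. Camera called 17 of 27 lists, 11 higher and 6 lower, and 0 calls held with an estimated correlation. Fry called 12, T and NK lymphoid among them. It did not call the osteocyte (adjusted p = 0.0560), proliferation (adjusted p = 0.0642), erythroid (adjusted p = 0.0655), megakaryocyte (adjusted p = 0.0657), oxidative phosphorylation (adjusted p = 0.296) or skeletal muscle list (adjusted p = 0.460).

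**Figure D2:**
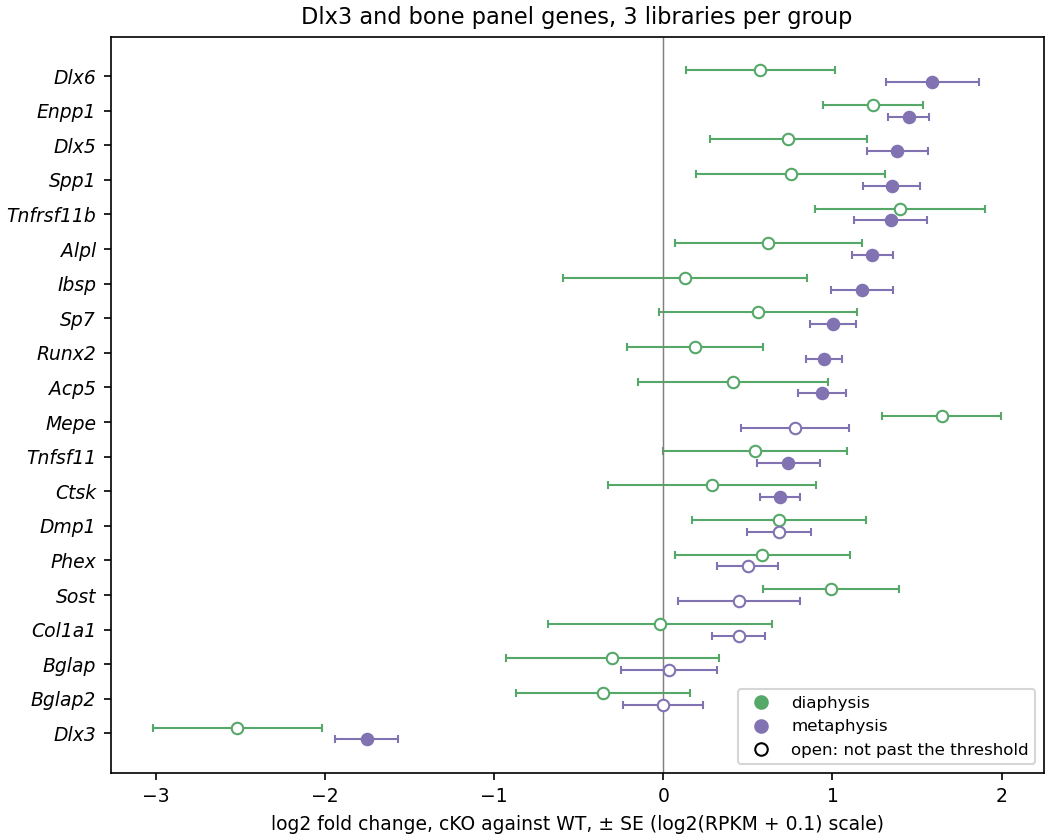
Log2 fold change of cKO against WT (log2(RPKM + 0.1) scale, bars ± SE, 3 libraries per group) for Dlx3 and the 19 measured panel genes, in the diaphysis and the metaphysis; filled points passed an adjusted p of 0.05. Spp1 was 1.35 ± 0.17 in the metaphysis and 0.75 ± 0.56 in the diaphysis, and the diaphysis bars were wider throughout.

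In the diaphysis, where the same question was asked with 6 further libraries, the genes with the smallest p again included Dlx3, Dlx4 and bone genes, but limma called 0 of 12540 genes (smallest adjusted p = 1.00; 86 at an unadjusted p under 0.05, where 627 would be expected by chance). The values that follow are therefore given without a call. Dlx4 was at 0.247 ± 0.125 RPKM in WT and 1.31 ± 0.19 RPKM in cKO (log2 2.09 ± 0.44). The osteocyte matrix gene Mepe was at 55.7 ± 27.3 and 161 ± 21.5 RPKM (SD, n = 3; log2 1.65 ± 0.35). Enpp1 (8.10 ± 3.15 and 18.3 ± 2.39 RPKM), the Wnt inhibitor Dkk1 (9.12 ± 4.96 and 26.3 ± 4.95 RPKM), Sost (log2 0.99 ± 0.40) and Tnfrsf11b (2.78 ± 1.65 and 6.48 ± 1.35 RPKM) had every cKO value above every WT value. Phlda1 (0.80 ± 0.16), Syt12 (1.35 ± 0.30), Angpt4 (0.81 ± 0.18) and Epcam (1.37 ± 0.32) had the smallest p on the higher side. Cd300ld (-1.56 ± 0.30), Serping1 (-1.14 ± 0.34), Gimap3 (-0.78 ± 0.24), Apol8 (-0.70 ± 0.22) and Adh1 (-0.52 ± 0.17) had the smallest p on the lower side. Of the tested genes 3.03% did not overlap between genotypes, below the 10% that chance gives. WT replicate 1 stood apart from the other 5 libraries. Its osteoblast list score was -1.40, against 0.36 and 0.79 in the other WT libraries. Its erythroid score was 0.78, and its Col1a1 level was 1801 RPKM against 8279 and 11230. Without it limma still called 0 genes (570 at an unadjusted p under 0.05, smallest adjusted p = 0.0933).

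Camera called 14 of 27 lists in the diaphysis, 9 higher and 5 lower, fry called 0, and 0 held with an estimated correlation (smallest adjusted p = 0.716). Members of the mineralization list averaged 0.58 and those of the osteocyte list 0.52, each with 2 members higher when adjusted over the list alone. For mineralization Vdr, the vitamin D receptor gene, was at 11.4 ± 7.61 RPKM in WT and 29.3 ± 6.29 RPKM in cKO (camera adjusted p = 1.32e-09; adjusted p = 0.716 with an estimated correlation). For osteocytes Fam20c was at 9.74 ± 5.26 and 19.9 ± 1.06 RPKM (camera adjusted p = 6.36e-06; adjusted p = 0.716 with an estimated correlation). Both calls were lost without WT replicate 1, with means of 0.072 and 0.086. The list means were 0.39 for homeobox and bone transcription factors (1 higher adjusted over the list alone), 0.25 for Wnt genes and 0.19 for BMP and TGF-beta genes, each with adjusted p = 0.949 with an estimated correlation. Without WT replicate 1 camera placed the same lists lower, with means of -0.15 (adjusted p = 0.0112), -0.29 (adjusted p = 0.000153) and -0.20 (adjusted p = 0.00339), each with adjusted p = 0.551 with an estimated correlation. The first 2 calls were lost without cKO replicate 1, and the call of BMP and TGF-beta genes without any 1 of the cKO libraries. Interferon response averaged 0.20, with Xaf1 at 0.82 ± 0.31, and oxidative phosphorylation 0.10, each with adjusted p = 0.949 with an estimated correlation. Without WT replicate 3 these means were -0.11 and -0.020. The interferon mean was also -0.11 without cKO replicate 2 and its call was lost without WT replicate 2, and the oxidative phosphorylation list was placed lower without cKO replicate 1 (mean -0.0033, camera adjusted p = 0.00648; 0.903 with an estimated correlation). Camera placed the endothelial list higher (mean 0.21, 0 of 22 past, adjusted p = 0.716 with an estimated correlation and 0.991 by fry; 0.063 and not called without WT replicate 1). The lists placed lower were B lymphoid (mean -0.24, adjusted p = 0.794 with an estimated correlation), with Igj at -1.57 ± 0.44, and monocyte and macrophage (-0.24; 0.059 without cKO replicate 1). The others were T and NK lymphoid (-0.29), adipocyte (-0.26) and tendon, periosteum and fibroblast (-0.10; 0.24 without WT replicate 2 or WT replicate 3). The B lymphoid and T and NK calls were lost without WT replicate 1, the adipocyte call without WT replicate 2, cKO replicate 2 or cKO replicate 3, and the tendon call without cKO replicate 3. All 15 measured replication-dependent histone genes had a positive sign (mean 1.10, camera adjusted p = 1.34e-13; adjusted p = 0.716 with an estimated correlation). Most histone transcripts lack a poly(A) tail, and the list was fixed as a sign of RNA and library quality. Its score was 1.51 in cKO replicate 1 and between -0.13 and 0.27 in the other cKO libraries; without cKO replicate 1 the mean was 0.54 and the call was lost.

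Camera did not call the osteoblast list in the diaphysis (mean 0.16, adjusted p = 0.159), the osteoclast list (mean 0.18), the osteoclast regulators (0.20), the chondrocyte list (0.079, with 1 member higher adjusted over the list alone), bone matrix (0.052), proliferation (-0.043), glucocorticoid and stress response (0.052), skeletal muscle (0.10), erythroid (-0.065), neutrophil (-0.071), megakaryocyte (0.038, where the median was -0.00018 and the test pointed down), peripheral nerve (0.074) or ribosomal proteins (0.039). Each of these lists but peripheral nerve was called in at least 1 of the 6 fits that left out a library, and for some the direction turned with the library. Without WT replicate 1 camera placed bone matrix (mean -0.70, adjusted p = 2.88e-27), osteoblast (-0.49, adjusted p = 4.93e-08) and chondrocyte genes (-0.62, adjusted p = 3.04e-08) lower and proliferation (0.22), erythroid (0.31) and megakaryocyte genes (0.47) higher, 0 of them with an estimated correlation. Without WT replicate 3 it placed these 6 lists the opposite way, with means of 0.54, 0.60, 0.50, -0.23, -0.31 and -0.28. Skeletal muscle was placed lower without cKO replicate 1 (-0.33) and higher without cKO replicate 3 (0.58), glucocorticoid and stress response lower without cKO replicate 3 (-0.17) and higher without WT replicate 2 (0.33), chondrocyte genes lower without cKO replicate 1 (-0.045) and erythroid genes higher without cKO replicate 2 (0.13). Skin again had 2 measured genes. Of the bone panel 2 genes were higher when adjusted over the list alone, and the panel mean was 0.56.

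**Figure D3:**
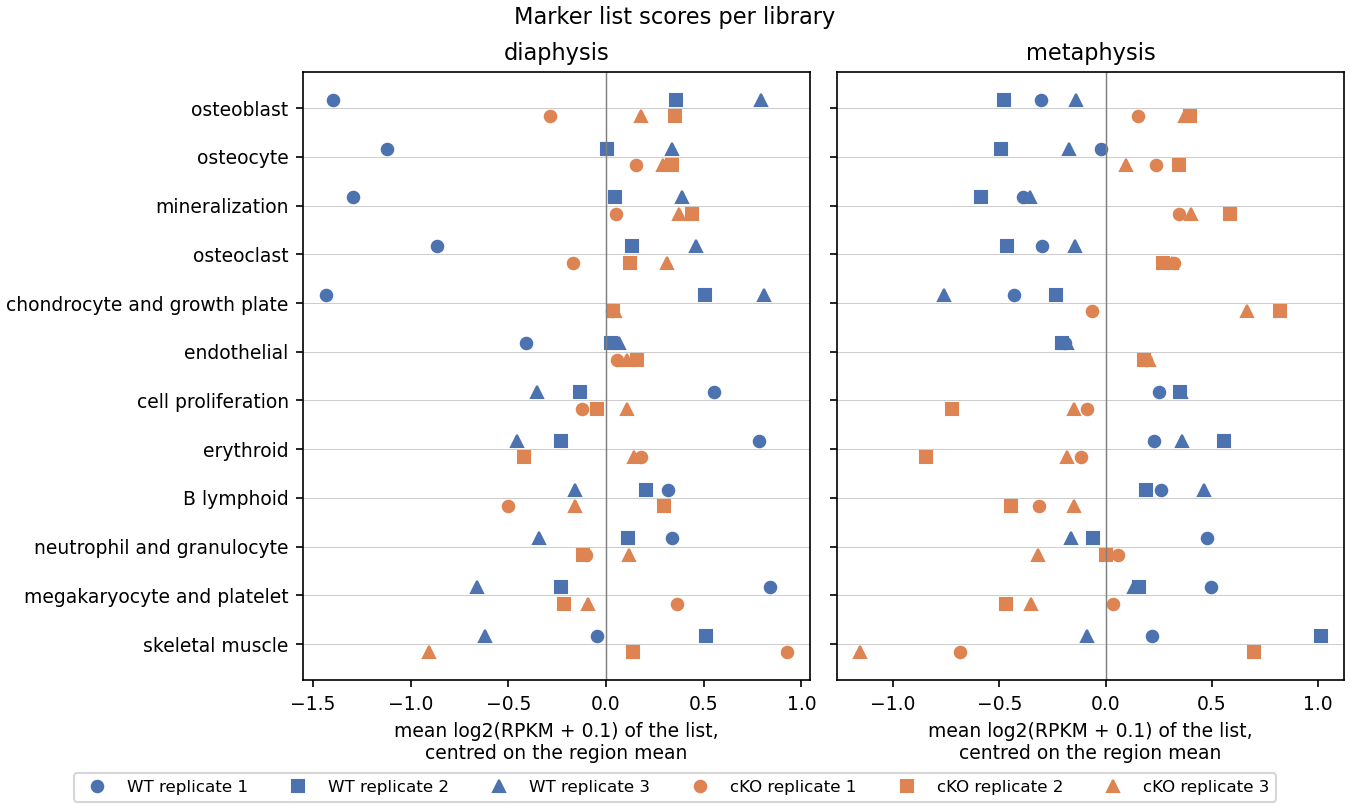
Score of 12 marker lists in each library, the mean log2(RPKM + 0.1) of the list's genes centred on the region's mean (x axis); rows are lists, colours genotypes and shapes replicates. In the metaphysis every cKO library scored above every WT library for the osteoblast list and below for the erythroid list, and in the diaphysis WT replicate 1 lay far from the rest, at -1.40 for the osteoblast list.

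Whether the response to the deletion differed between the regions was tested as a contrast of the 2 within-region differences over all 12 libraries. Limma called 0 of 12859 genes (smallest adjusted p = 0.907; 523 at an unadjusted p under 0.05, 643 expected by chance), and without diaphysis WT replicate 1 it called 124. By camera 16 lists differed, 0 of them with an estimated correlation and 0 by fry. For the chondrocyte and growth plate list the genotype effect was lower in the diaphysis by a mean log2 difference of -1.38 over 24 members (adjusted p = 4.90e-10; adjusted p = 0.787 with an estimated correlation). Of these members 14 passed the filter in the diaphysis, and over those 14 the difference was -0.67. The replication-dependent histone genes differed by 1.12 over 19 members and by 1.33 over the 14 past the filter in both regions (adjusted p = 0.787 with an estimated correlation). Much of this rested on diaphysis cKO replicate 1, with a histone score of 1.51 against -0.13 and 0.27 in the other diaphysis cKO libraries. Proliferation genes (0.60) and erythroid genes (0.70) had a less negative effect in the diaphysis, each with adjusted p = 0.787 with an estimated correlation.

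Across regions, 0 genes passed in both, since the diaphysis had no calls. Of 1408 metaphysis calls also tested in the diaphysis, 79.6% had the same sign there, 802 of 917 that rose and 319 of 491 that fell. Pearson's r of the fold changes was 0.37 across 12321 genes, which are not independent replicates. An exact one-sided permutation of the diaphysis genotypes gave a share at least as large in 9 of 20 labelings (p = 0.45, smallest possible 0.05). The share was 22.3% without diaphysis WT replicate 1 and 96.4% without diaphysis WT replicate 3. A genotype effect common to both regions, fitted over all 12 libraries after the separate results were known, called 31 of 12859 genes, 26 higher and 5 lower. Dlx4 (2.23 ± 0.21 SE, adjusted p = 0.00183), Cd300ld (-1.67 ± 0.18, adjusted p = 0.00417), Enpp1 (1.34 ± 0.17, adjusted p = 0.00957) and Dlx3 (-2.14 ± 0.30, adjusted p = 0.0115) were among them. The count was 16 to 20 when any metaphysis library was left out, 18 and 19 without diaphysis cKO replicates 1 and 3, and 104 without diaphysis WT replicate 3. With the metaphysis genotypes kept, 3 of the 20 labelings of the diaphysis libraries gave at least 31 genes, the real one included. The highest other gave 1815, so the count of 31 does not show an effect in the diaphysis. A count does not settle single genes, and the labelings with 1815 and 708 genes shared 0 and 11 of the 31.

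The WT levels of the 2 regions came from separately made tables and are set side by side without a test. The genes given here were chosen after their values were seen. Col2a1 was at 105 ± 65.6 RPKM in the diaphysis and 495 ± 159 RPKM in the metaphysis. Col10a1, a gene of hypertrophic chondrocytes, was at 7.01 ± 5.47 and 166 ± 49.8 RPKM, and Ihh at 0.359 ± 0.20 and 2.10 ± 0.14 RPKM (SD, n = 3). Dlx3 was at 7.97 ± 4.93 and 9.11 ± 0.86 RPKM, Col1a1 at 7103 ± 4823 and 7425 ± 1082 RPKM, and Mepe at 55.7 ± 27.3 and 41.0 ± 17.7 RPKM.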

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

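The weighing tests of the metaphysis bone and marrow lists and of diaphysis WT replicate 1, the test of shared reads at Dlx4, the counts over other splits of the single regions and of their difference, the covariate fit with the osteoblast score, the list differences over members past the filter in both regions, the labelings that keep the metaphysis genotypes and the lists of the difference without a library were chosen after the results were seen.

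The genotype effect differed between the regions for 16 lists by camera at the preset correlation, though for 0 with an estimated correlation (smallest adjusted p = 0.787) and for 0 by fry. As mean log2 differences, diaphysis effect minus metaphysis effect, the bone lists were -0.43 for osteoblasts, -0.31 for mineralization, -0.28 for homeobox and bone transcription factors, -0.42 for osteoclasts, -0.21 for Wnt signalling, -0.25 for BMP and TGF-beta signalling and -0.28 for bone matrix. The chondrocyte and growth plate list was at -1.38 (-0.67 over the 14 of 24 members past the filter in the diaphysis) and the endothelial list at -0.17. On the positive side were proliferation (0.60), oxidative phosphorylation (0.31), skeletal muscle (0.86), erythroid (0.70), B lymphoid (0.36), megakaryocyte (0.56) and replication-dependent histone genes (1.12; 1.33 over 14 members past the filter in both regions). Without diaphysis WT replicate 1, 20 lists differed. The sizes of these differences depend on single diaphysis libraries. The diaphysis osteoblast mean was -0.49 without WT replicate 1 and 0.60 without WT replicate 3, against 0.61 in the metaphysis. The diaphysis histone score was 1.51 in cKO replicate 1 and -0.13 and 0.27 in the other cKO libraries.

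In the metaphysis, camera placed bone lists higher and erythroid, B lymphoid and megakaryocyte lists lower in cKO, with 0 of these calls held at an estimated correlation (adjusted p = 0.347 for osteoblast, 0.407 for erythroid, 0.270 for B lymphoid and 0.433 for megakaryocyte). A larger share of osteoblasts alone with unchanged expression per cell would move genes of these cells by a like amount, yet 12 of 21 members departed from the list mean (adjusted p under 0.05 over the list alone). Of these, 6 lay above, among them Bmp3 (0.92) and Pth1r (0.85), and 6 below, among them Omd (-0.74) and Bglap2 (-0.62), although Atf4, Spp1 and some others are expressed in other cells too. In the erythroid and B lymphoid lists the same test called no member (smallest adjusted p = 0.909 and 0.0947). A common shift of these marrow lists is therefore not argued against. Admixed muscle is argued against by an osteoblast mean of 0.585 with the muscle score as a covariate (0.614 without). Depths overlapped between the genotypes, with 2 of 3 cKO libraries deeper than the shallowest WT library. The shallowest library was still cKO (24.8 M reads) and the deepest WT (35.0 M), so this overlap does not decide on depth. With the marrow score as a covariate the Dlx3 difference went from -1.75 ± 0.18 to -2.37 ± 0.49 with a larger SE and no call, while the osteoblast mean went from 0.61 to 0.29 and 8 named genes reversed. Of these, 4 (Gata1, Ermap, Alas2, Tfrc) belong to the erythroid list in that score, so their reversal is largely fixed by its construction. The others were Nrip3 and the proliferation genes Pcna, Birc5 and Top2a. The proliferation list mean went from -0.64 to 0.30 with the same score. A different marrow part of the dissection and an effect of the genotype stay open and were not tested; a 10-split count is too small to go under 0.05 (1 of 10 splits reached the real 1441 genes, the highest other gave 0).

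Diaphysis WT replicate 1 lay apart from the other 5 libraries. It was the highest in 4 of 5 marrow lists and the lowest in all 4 bone lists, which may reflect more marrow and less bone in that sample, but this cannot be told apart from other causes because no record of the dissection is at hand and the marrow scores ranged from 0.09 for monocytes to 0.84 for megakaryocytes. Shallow sequencing is argued against, since the shallowest library, cKO replicate 1, scored 1.11 above it on the osteoblast list. A cKO library under a WT name is argued against as well, since Dlx3 relative to the osteoblast mean lay 2.76 log2 units above the highest cKO library. The real diaphysis split gave 0 genes and the highest of the other splits 0; a real count of 0 is reached by 10 of 10 splits by construction, so the splits decide nothing here.

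Dlx4 rose in the metaphysis beside a lower Dlx3, its neighbour on chromosome 11. Reads shared between the genes would lower Dlx4 with Dlx3, and its log2 fold change of 2.37 argues against that. A larger share of osteoblasts alone is argued against by a rise of 1.76 ± 0.25 (SE) relative to the osteoblast mean. A chromosome segment that differs between the genotypes cannot be told apart: within 5 Mb of Dlx3 16 of 98 genes passed and elsewhere 1396 of 12295, an odds ratio of 1.52 (95% confidence interval 0.829 to 2.63, Fisher's exact test, 2-sided p = 0.148), an interval too wide to decide. A segment reaching beyond 5 Mb was not tested, and Cd300ld lies on chromosome 11 outside that window. An effect of the genotype stays open and was not tested apart from these causes.

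For the difference between regions the real split gave 0 genes, which 100 of 100 drawn splits reach by construction, so the splits decide nothing; the highest other gave 16. For the effect fitted as common to both regions, 2 of 100 splits of all 12 libraries reached the real 31 genes, which excludes chance at 0.05 only against no effect in either region, since nearly all splits also break up the metaphysis genotypes. The highest other split gave 708 genes. With the metaphysis genotypes kept, 3 of 20 labelings of the diaphysis libraries gave at least 31 genes and the highest other gave 1815. The count therefore does not show an effect in the diaphysis, though it does not settle single genes. The high counts point to a structure of the diaphysis libraries that runs along the metaphysis contrast.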

How the results depend on the processing

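Fits with the osteoblast score, the highest transcript per symbol, scaling without globin or metaphysis calls alone, and all tests of the common effect, were chosen after seeing the data. So were all alternatives of the same-sign share and of the list differences. Except where a cause is named, the cause was not tested. For single genes 1625 diaphysis values and 1490 metaphysis values were kept, and 16 and 28 newly passed. A value that passed in both the main fit and the alternative was kept if its sign was the same. A value that passed in neither was kept if it moved by no more than the gene's SD within groups, whatever its sign. Another 322 metaphysis values no longer passed, 14 and 28 others moved and 11 metaphysis values reversed. For lists the counts kept were 461 and 517, with 49 and 35 lost, 25 and 6 gained and 30 and 8 reversed. A list called in neither fit counted as kept whatever its direction. Genes that fell below the filter without a library have no value there.

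Genes past the threshold in the diaphysis numbered 58 with array weights, whose estimate did not converge, and 1 with the osteoblast score as a covariate, and 0 without any library. In the metaphysis they numbered 789 without a filter (18575 genes tested), 2813 with array weights, 2745 at an adjusted p of 0.1 and 904 at 1.5-fold. They numbered 8 with all 12 libraries in 1 fit (a larger spread from the diaphysis), 0 with the marrow score, 0 with the osteoblast score and 105 to 1418 without a library. With the muscle score they were 784 higher and 881 lower. The difference between regions gave 2 without a filter, 1 with a pseudocount of 1, 2402 with array weights and 0 to 124 without a library. The common effect gave 50 with quantile normalization, 19 at 5 RPKM, 130 with the osteoblast score and 16 to 104 without a library. The same-sign share was 83.7% without a filter, 75.0% at 5 RPKM, 73.0% at an adjusted p of 0.1 and 22.3% to 96.4% without a library.

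Dlx3 in the diaphysis passed with array weights (-2.52) and with the osteoblast score (-2.66). In the metaphysis it no longer passed with all 12 libraries in 1 fit (-1.75), the marrow score (-2.37) or the osteoblast score (-2.52). Metaphysis genes that reversed with the marrow score were Nrip3 (0.32), Pcna (0.030), Birc5 (0.11), Top2a (0.25), Gata1 (0.23), Ermap (0.34), Alas2 (0.21) and Tfrc (0.20), and with the osteoblast score Tnfsf11 (-0.079), Myh1 (0.071) and Alas2 (0.11). These covariates move with the genotype, and the erythroid list, which holds Gata1, Ermap, Alas2 and Tfrc, is part of the marrow score.

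With an estimated correlation 0 lists were called in the diaphysis, 0 in the metaphysis and 0 for the difference, and with the marrow score 9 in the metaphysis. Diaphysis lists that reversed with the marrow score were osteoblast (-0.16), Wnt (-0.023), BMP and TGF-beta (0.0035, the test pointing down), chondrocyte (-0.27), bone matrix (-0.32), proliferation (0.10) and megakaryocyte (0.25). With the osteoblast score bone matrix (-0.13) and megakaryocyte (0.15) reversed, and without a filter chondrocyte (-0.43). Metaphysis lists that reversed with the marrow score were bone matrix (-0.060), proliferation (0.30), erythroid (0.25) and megakaryocyte (0.35), and with the osteoblast score monocyte (0.36), adipocyte (1.42) and tendon (0.64). Ranges of diaphysis list means without a library were -0.49 to 0.60 for osteoblast, -0.15 to 0.71 for homeobox, -0.29 to 0.60 for Wnt, -0.20 to 0.44 for BMP and TGF-beta, -0.62 to 0.50 for chondrocyte and -0.70 to 0.54 for bone matrix. For proliferation the range was -0.23 to 0.22 and for glucocorticoid -0.20 to 0.33. They were -0.11 to 0.48 for interferon, -0.020 to 0.19 for oxidative phosphorylation, -0.33 to 0.58 for muscle, -0.31 to 0.31 for erythroid, -0.28 to 0.47 for megakaryocyte and -0.79 to 0.24 for tendon. In the metaphysis the interferon mean ran from -0.31 to 0.24. Depth limits genes well below 1 RPKM most in diaphysis cKO replicate 1, the shallowest library at 18.6 M reads.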

Other observations

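The fit of an effect common to both regions was chosen after the separate results were seen, and its count over other splits was predicted before it was run. The genes of its 31 given here were chosen after their values were seen. Each effect is the mean of those in the 2 regions, which can differ in size, as for Apol8 (-0.70 in the diaphysis and -1.56 in the metaphysis). In diaphysis WT, Ihh was at 0.359 ± 0.20 RPKM, below the RPKM minimum of 1, so its diaphysis effect is uncertain. Ihh, the growth plate hedgehog ligand, was higher by 1.56 ± 0.21 on the log2 scale (SE, adjusted p = 0.00957), the Wnt inhibitor Dkk1 by 1.46 ± 0.25 (adjusted p = 0.0362), the growth factor gene Pdgfa by 1.27 ± 0.23 (adjusted p = 0.0409) and the vitamin D receptor gene Vdr by 1.64 ± 0.28 (adjusted p = 0.0362). The mineralization phosphatase Phospho1 was higher by 1.03 ± 0.18 (adjusted p = 0.0409). Of genes of matrix proteins or proteases, Emilin3 (2.30 ± 0.31), Ltbp2 (1.55 ± 0.25), Adamts15 (1.46 ± 0.23) and Adamts18 (1.85 ± 0.30) were higher. The cell surface genes Cadm1 (1.29 ± 0.18), Gfra1 (1.00 ± 0.14) and Tspan6 (1.10 ± 0.15) were higher, as were the crystallin genes Cryba4 (1.55 ± 0.24) and Crybb1 (1.79 ± 0.31). On the lower side, beside Dlx3 and Cd300ld, were Apol8 (-1.13 ± 0.20, adjusted p = 0.0409) and Thbs1 (-0.56 ± 0.10, adjusted p = 0.0391). With the metaphysis genotypes kept, 3 of 20 labelings of the diaphysis libraries gave at least 31 genes, so the count of these calls does not show an effect in the diaphysis. It does not settle single genes.

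The beta-globin transcripts were split differently in the 2 tables. In WT, Hbb-b1 was at 18396 ± 19697 RPKM in the diaphysis and 1127 ± 183 RPKM in the metaphysis, Hbb-b2 at 30649 ± 11354 and 4143 ± 1066 RPKM, and Beta-s at 4230 ± 2360 and 38451 ± 6345 RPKM (SD, n = 3), while the alpha-globin Hba-a1 was at 24949 ± 12331 and 21774 ± 1244 RPKM. These beta-globin transcripts are near-identical copies or forms of a gene, and the tables were made separately. Within the diaphysis alone Hbb-b1 was at 41116 RPKM in WT replicate 1 and at 7950 and 6123 RPKM in WT replicates 2 and 3. That difference lies within 1 table, and its cause was not tested.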
